A study of Mus musculus with 71 samples.

How the data were processed

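Small RNA libraries of 3 brain regions of male mice were analysed: left cortex, left striatum and right cerebellum. The mice were wild type (WT) or DYT1KI, a knock-in model of DYT-TOR1A dystonia. Each mouse was either naive or had received a crush of its right sciatic nerve, which lasted 1 minute and was done at 12 weeks of age, per the labels' protocols. Tissue was taken 12 weeks after the injury, per the labels. The 12 groups of tissue, genotype and treatment held 6 libraries each, except the cerebellum of injured WT mice with 5, which gave 71 libraries from 24 numbered animals. The number in a library's name was taken as the animal, since the same numbers recur in the 3 tissues of a group. The labels also give each library a biological replicate number (biol rep) from 1 to 6 that recurs in every group and stands for a different animal in each. Single libraries are named below by group and biol rep. In injured WT mice each biol rep of the cerebellum is another animal than in cortex and striatum. Replicates of a group were therefore taken as separate mice.

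RNA was isolated with a miRNeasy mini kit from the cerebellum and a miRNeasy micro kit from cortex and striatum, and libraries were made with the QIAseq miRNA UDI kit, per the labels' protocols. R 4.1.0 and featureCounts 1.6.4 were among the software, per the submitters' processing notes, which give them no role. The aligner, the genome build, the miRNA annotation and the use of molecular identifiers are not given in the sources used here. The authors deposited 12 tables, 4 per tissue, each made with DESeq2 per the file headers and each listing 1927 mature miRNAs, of which 1085 had a count in any library. The count columns hold whole raw counts per mature miRNA, per the file headers, and were identical in the 4 tables of a tissue. The normalized columns and the mean over libraries are a signal that the authors made by dividing each count by 1 size factor per library within a tissue. The authors' log2 fold change and its standard error compare the group named first with the one named second, and the fold changes were smaller in size than the ratios of the group means. A score, the Wald statistic of each miRNA, stands beside them in the authors' tables. The unadjusted p-value and its Benjamini-Hochberg adjusted form are also the authors' columns, empty where DESeq2 gave none. No column of per-library values was left unmapped.

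All tests started from the deposited counts. In R 4.3.3 with edgeR 4.0.16, the 4 groups of a tissue were fitted together with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the robust quasi-likelihood test. The p-values were adjusted by the Benjamini-Hochberg method over all miRNAs tested in a tissue. This kept 530 miRNAs in cortex, 547 in striatum and 555 in cerebellum. An adjusted p under 0.05 was the threshold. In each tissue 7 comparisons were made: DYT1KI against WT in naive and in injured mice, injured against naive mice in WT and in DYT1KI, the injury effect averaged over genotypes, the genotype effect averaged over treatments, and the interaction. The 3 tissues of naive WT mice were compared in a fit of their own (534 miRNAs), where a call also needed an absolute log2 fold change of at least 1. Whether an effect differed between tissues was tested with limma 3.58.1 (voom, with the correlation between tissues of the same animal estimated) over 629 miRNAs. Log2 CPM values for plots and lists used a prior count of 2, and levels are given as CPM after TMM scaling.

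For miRNA groups, 21 lists were fixed: neuron-enriched, neuronal-activity-regulated, the imprinted Dlk1-Dio3 clusters of chromosome 12, oligodendrocyte, microglia and inflammation, blood cells, endothelium and vessel wall, choroid plexus and ependyma, Htr2c-hosted, the miR-200 family, the miR-183 cluster, muscle, Hox clusters, pituitary and hypothalamus, ER-stress and unfolded-protein-response linked, peripheral nerve injury, the let-7 family, the miR-17-92 cluster and its paralogs, and the miR-29, miR-30 and miR-181 families. Lists with at least 3 measured members (19 in cortex and striatum, 21 in cerebellum) were tested against the other miRNAs with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and on their own with fry. Members of a list were also counted with p-values adjusted over the list alone. The lists share members, and most of their miRNAs are counted in every tissue.

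The miRNAs named in the text follow a rule. For each comparison these are all miRNAs past the threshold if at most 10 rose or fell, otherwise the 10 per direction with the smallest adjusted p. Where fewer than 3 passed in a direction, the 3 with the smallest unadjusted p in it are given as values that did not pass. Each list gives its members past the threshold, otherwise up to 3 with the smallest p. miR-132-3p, miR-212-3p, miR-21a-5p, miR-146a-5p, miR-155-5p, miR-124-3p and miR-9-5p are always included. Groupings, tests, lists, this rule and most alternatives were chosen before the data were examined. Names outside the rule are marked where they occur.

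In 35 rows the tables join the names of several mature miRNAs, whose counts cannot be told apart. Members of the let-7, miR-29, miR-30, miR-181 and miR-200 families differ by few bases, so their separate values are uncertain where the counting split reads between near copies. Depth ran from 5182284 to 12582875 counts per library and 585 to 691 miRNAs were detected per library. Without known use of molecular identifiers, counts are not proven to be independent molecules. No pair of replicates agreed within counting noise: the lowest chi-square per degree of freedom was 16.37. Libraries of the same mouse from different tissues were compared in naive WT mice, where the deviations from the tissue means had a mean correlation of 0.12 over 18 pairs, with 7 pairs above 0.1.

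The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 miRNAs changed. Of miRNAs changed 1.5-fold, 2-fold and 4-fold, the simulated injury effect averaged over genotypes recovered 67.2%, 86.2% and 95.4% in cortex (518 miRNAs tested), 81.5%, 88.7% and 95.1% in striatum (531) and 68.8%, 81.8% and 100% in cerebellum (537). For the simulated comparison of injured with naive WT mice these shares were 38.8%, 70.8% and 90.8% in cortex, 67.7%, 85.5% and 95.1% in striatum and 42.2%, 68.2% and 91.5% in cerebellum. False calls numbered 2 to 4 among the 321 to 348 unchanged miRNAs of a tissue, and 0 in the simulated genotype comparison of naive mice. A shifted list was found by camera in simulated striatum data at an adjusted p of 4.66e-43, and 0 random lists were called among the 21 tested. Each miRNA was drawn on its own there, so this says nothing on lists whose members vary together.

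Alternatives to the settings were DESeq2 size factors and upper-quartile scaling in place of TMM, no filter, a filter at 10 CPM, the DESeq2 1.42.0 Wald test, limma voom, only the 2 groups compared, the biol rep number as a block, the range of animal numbers as a term, each library left out in turn, other prior counts (0.5 and 5), an estimated correlation for lists, and for the authors' tables an adjusted p under 0.1 or a minimum fold of 1.5. After the data had been seen, 7 more were added: a term for biol rep 1 to 3 against 4 to 6, each of these ranges alone, a composition score as a term, no miRNAs that are at 0 in part of the libraries of a tissue and at 50 counts or more in the rest, and the cortex injury effect without libraries that held miR-24-3p or without libraries rich in marker miRNAs of other tissue. The composition score of a library is its position along the difference between biol rep 4 to 6 and biol rep 1 to 3 of another tissue (the cerebellum for cortex, the cortex for the others), scaled so that 1 equals that difference. The range of animal numbers is uneven over the groups, since only animal 31 of the naive WT mice falls in the low range. Calls with this term are therefore not read as better adjusted. Biol rep numbers follow the order of the animal numbers in each group. In cortex and striatum biol rep 1 to 3 are the low-numbered and 4 to 6 the high-numbered animals, except in naive WT mice. In cerebellum injured WT mice are an exception too. The biol rep range and the animal number range therefore largely overlap. GC content came from precursor sequences in the GENCODE vM21 transcripts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots. Target genes, precursor positions and other RNA classes were not analysed here.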

Results

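MicroRNAs were counted in the cortex, striatum and cerebellum of WT and DYT1KI mice, either naive or 12 weeks after a crush of the sciatic nerve. DYT1KI mice carry a dystonia mutation of torsinA, an ATPase of the endoplasmic reticulum and nuclear envelope. The design asks how nerve injury, the mutation and both together change brain miRNAs. Each group held 6 mice, except the cerebellum of injured WT mice with 5. Total counts per library ran from 5182284 to 10064827 in cortex, from 6161668 to 10219295 in striatum and from 8199033 to 12582875 in cerebellum. The 10 most abundant miRNAs took 56.4% to 65.9% of the counts in cortex, 53% to 59.1% in striatum and 64.6% to 78.6% in cerebellum. A count of 3 corresponds to 0.579 CPM in the shallowest library. As far as counting error goes, a miRNA below this level was not detectable there.

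The comparison of tissues in naive WT mice (6 libraries each) shows which miRNAs mark each region without injury or mutation. miR-206-3p, best known from skeletal muscle, was 7.33 ± 0.16 log2 units (estimate ± SE) higher in cerebellum than in cortex, at 2580 ± 339 CPM (mean ± SD) against 16 ± 2.62 (adjusted p = 4.15e-18). It was 3.98 ± 0.14 higher in striatum than in cortex (adjusted p = 8.69e-15). miR-10a-5p and miR-10b-5p, which lie within Hox gene clusters that pattern the hindbrain, were higher in cerebellum than in cortex by 5.32 ± 0.25 and 4.54 ± 0.30. In striatum miR-10b-5p was at 0 in 2 of 6 libraries and had 3 to 5 counts in the others, against 39 to 86 counts in cortex, so no fold is given there. miR-187-3p reached 5720 ± 265 CPM in striatum against 537 ± 101 in cerebellum. Its log2 difference between striatum and cortex was 5.31 ± 0.16 (adjusted p = 1.09e-15). miR-132-3p, induced by CREB with neuronal activity, was highest in cortex at 1630 ± 535 CPM. It was lower in striatum (-2.07 ± 0.27, adjusted p = 4.27e-06) and in cerebellum (-3.98 ± 0.30, adjusted p = 6.38e-10). Each of these differences separated all 6 libraries of one tissue from all 6 of the other.

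Some of the fixed lists differed between regions in 1 direction and others did not, among 236 of 534 miRNAs called between cerebellum and cortex. All 3 members of the miR-183 cluster, known from sensory organs, were higher in cerebellum than in both other tissues. Over cortex the difference was 4.22 ± 0.21 for miR-183-5p (adjusted p = 1.4e-12) and 4.59 ± 0.24 for miR-182-5p (adjusted p = 4.37e-12). The Htr2c-hosted miRNAs, from introns of a serotonin receptor gene, were higher in striatum and in cerebellum than in cortex for 5 of 5 members, with miR-448-3p at 5.37 ± 0.29 between cerebellum and cortex. All 7 choroid plexus and ependyma miRNAs were higher in cerebellum than in cortex, among them miR-449a-5p of multiciliated cells (2.19 ± 0.13). miR-449a-5p was yet highest in striatum, at 213 ± 17.5 CPM against 43.9 ± 5.05 in cerebellum and 9.62 ± 1.73 in cortex. The list had 6 members higher and 1 lower in cerebellum than in striatum, and 1 higher and 2 lower in striatum than in cortex. Of the 9 neuronal-activity-regulated miRNAs 6 were lower in cerebellum than in cortex and 4 were lower in striatum than in cortex. The imprinted Dlk1-Dio3 clusters had 19 of 41 members lower in cerebellum than in cortex and 0 higher, and 8 lower and 4 higher in striatum than in cortex. Between cerebellum and cortex the ER-stress list (3 higher, 5 lower) and the nerve injury list (5 higher, 4 lower) went both ways. The let-7 and miR-29 families had 0 members past the threshold of 1 log2 unit between these tissues. Between cerebellum and striatum 1 let-7 member passed, let-7g-5p (1.07 ± 0.11, adjusted p = 5.52e-08). Adjusted over the list alone, each of these counts was the same. Among neuronal miRNAs, miR-138-5p, which limits dendritic spine growth, was highest in striatum (1.63 ± 0.11 over cortex, adjusted p = 5.34e-10). miR-124-3p was lower in striatum than in cortex (-1.29 ± 0.18, adjusted p = 1.08e-05). miR-146a-5p, a brake on inflammatory signalling, was lower in cerebellum than in cortex (-1.82 ± 0.30, adjusted p = 2.76e-05). miR-155-5p, which promotes inflammation, was higher there (1.08 ± 0.22, adjusted p = 0.000246). A few miRNAs were at or near 0 in whole tissues and are given as counts. miR-615-3p had 14 to 30 counts in cerebellum and 0 in every naive WT library of cortex and striatum. miR-196a-5p had 8 to 31 counts in cerebellum and was found in 1 of 6 libraries of cortex (3 counts) and 1 of 6 of striatum (2 counts).

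With edgeR's quasi-likelihood test, 148 of 534 miRNAs differed between striatum and cortex (56 higher, 92 lower). The count was 236 between cerebellum and cortex (93 higher, 143 lower) and 223 between cerebellum and striatum (95 higher, the others lower). Of the named miRNAs past the threshold, all 6 libraries lay beyond all 6 of the other tissue for 50 of 60, 59 of 75 and 69 of 77. Upper-quartile scaling moved the median log2 difference from -0.042 to -0.209 (striatum against cortex) and from -0.121 to 0.243 (cerebellum against striatum), with 43 higher and 117 lower, and 137 higher and 89 lower. The cerebellum differs from the other tissues also in its side of the brain and its RNA kit, per the labels' protocols.

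**Figure D1:**
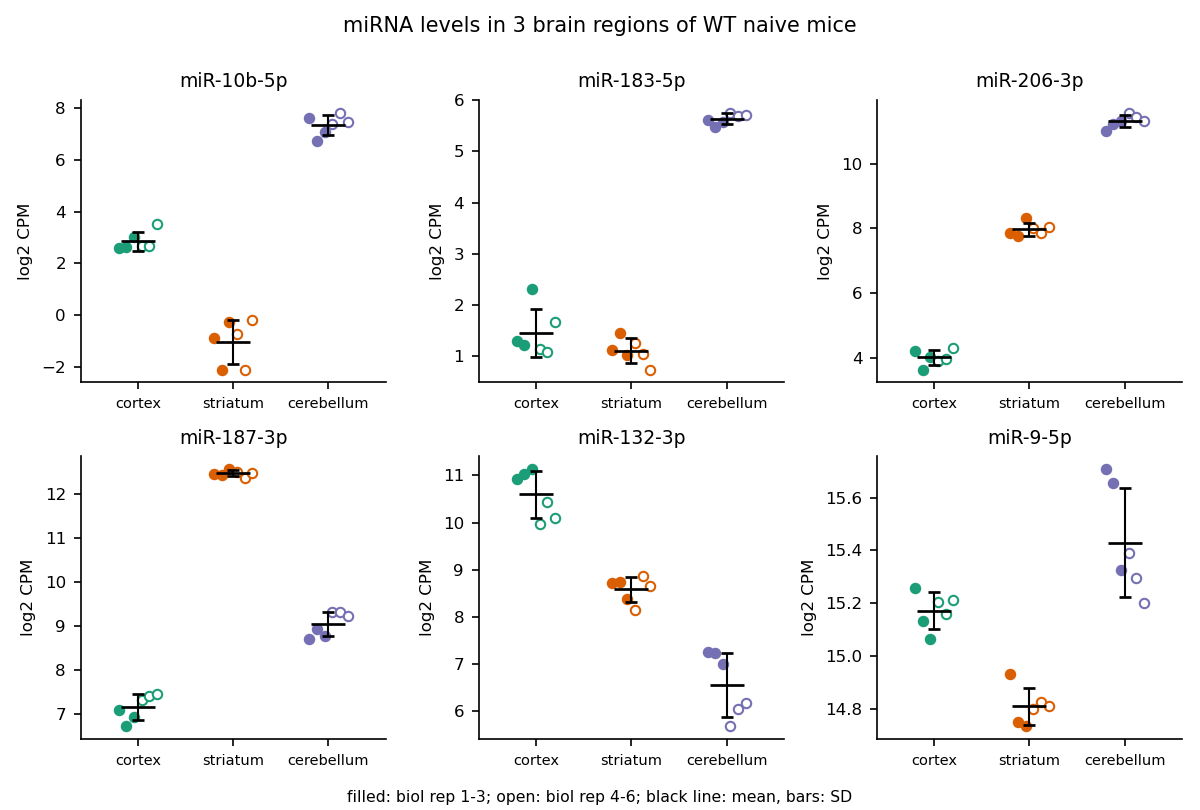
Log2 CPM of 6 miRNAs in cortex, striatum and cerebellum of naive WT mice, with 1 point per library (filled for biol rep 1 to 3, open for 4 to 6), a black line at the mean and bars of 1 SD (n = 6 per tissue). miR-206-3p, miR-10b-5p and miR-183-5p are highest in cerebellum, miR-187-3p in striatum and miR-132-3p in cortex. miR-9-5p, a miRNA of neural progenitors and neurons, differs by less than 1 log2 unit between the tissues.

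Averaged over genotypes, 106 of 530 cortical miRNAs fell and 58 rose after nerve injury (12 injured against 12 naive libraries). As given below, upper-quartile scaling turned this balance towards rises, and with the composition score as a term 0 passed. Of the lists only let-7 moved apart from the other miRNAs by camera, and not with an estimated correlation. miR-434-3p and miR-434-5p, from the imprinted Dlk1-Dio3 region, fell to 0.47 and 0.49 of the naive level (log2 -1.10 ± 0.25 and -1.03 ± 0.22, adjusted p = 0.0123 and 0.0121). They were lower in 11 and 12 of 12 injured libraries than the naive mean of their genotype. miR-30b-5p fell likewise (-1.04 ± 0.25, 0.49-fold, adjusted p = 0.0128, 12 of 12). miR-345-5p showed -1.46 ± 0.31 (adjusted p = 0.0121, 12 of 12). miR-423-5p rose 1.61-fold (0.68 ± 0.17, adjusted p = 0.0149, 12 of 12). Its level went from 160 ± 77.3 to 269 ± 62.1 CPM in DYT1KI mice (mean ± SD, n = 6) and reached 240 ± 40.3 CPM in injured WT mice. miR-212-3p, transcribed with miR-132 in active neurons, fell to 0.61 of the naive level (-0.71 ± 0.20, adjusted p = 0.0205, 10 of 12). miR-132-3p stood at -0.49 ± 0.23, which did not pass (adjusted p = 0.1).

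The let-7 family, which times development and represses Lin28 and Ras genes, had 5 of 9 members that rose and 0 that fell (8 adjusted over the list alone). let-7e-5p/7k rose 1.3-fold (0.37 ± 0.10, adjusted p = 0.0168, 12 of 12 libraries), let-7b-5p 1.28-fold (0.35 ± 0.11, adjusted p = 0.0258, 11 of 12) and let-7a-5p 1.2-fold (0.27 ± 0.10, adjusted p = 0.0367, 10 of 12). Its camera test gave an adjusted p of 0.00349, but an adjusted p = 0.911 with an estimated correlation. In the imprinted Dlk1-Dio3 clusters 13 of 41 members fell and 4 rose (18 adjusted over the list alone). miR-543-3p was at -1.20 ± 0.38 (adjusted p = 0.0239, 10 of 12) and miR-136-5p at -1.05 ± 0.37 (adjusted p = 0.0359, 10 of 12). With the composition score as a term both turned direction (0.06 and 0.16), as did miR-329-3p, miR-410-3p, miR-494-3p and miR-496a-3p of these clusters. Against these, miR-485-5p rose 1.53-fold (0.61 ± 0.19, adjusted p = 0.0209, 12 of 12).

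Of 10 microglia and inflammation miRNAs 4 fell and 1 rose (6 adjusted over the list alone). The myeloid miR-223-3p fell to 0.71 (-0.49 ± 0.13, adjusted p = 0.0154, 12 of 12), the lymphocyte miR-150-5p to 0.68 (-0.56 ± 0.16, adjusted p = 0.0205, 9 of 12) and miR-146a-5p to 0.63 (-0.68 ± 0.21, adjusted p = 0.0219, 9 of 12). miR-155-5p rose 1.39-fold (0.48 ± 0.13, adjusted p = 0.0193, 11 of 12), and miR-21a-5p had a log2 change of -0.16 ± 0.10 (adjusted p = 0.215). Of 10 neuron-enriched miRNAs 5 fell and 1 rose (6 adjusted over the list alone). miR-218-5p, abundant in motor neurons, fell to 0.69 (-0.54 ± 0.14, adjusted p = 0.0148, 11 of 12), miR-153-3p to 0.64 (-0.63 ± 0.17, adjusted p = 0.0154, 11 of 12) and miR-9-5p to 0.89 (-0.16 ± 0.06, adjusted p = 0.0407, 10 of 12). miR-129-5p rose 1.33-fold (0.41 ± 0.14, adjusted p = 0.028, 11 of 12), and miR-124-3p, the most neuron-specific of them, had 0.06 ± 0.11 (adjusted p = 0.697). The activity list had 2 of 9 members that fell and 1 that rose (3 adjusted over the list alone). Of the miR-29 family, which represses collagens, 2 of 3 members fell (2 adjusted over the list alone). These were miR-29c-3p to 0.69 (-0.54 ± 0.14, adjusted p = 0.0154, 12 of 12) and miR-29a-3p to 0.8 (-0.32 ± 0.10, adjusted p = 0.0252, 8 of 12). Of the miR-30 family 2 of 5 fell (2 adjusted over the list alone), miR-30b-5p and miR-30c-5p (-1.11 ± 0.30, adjusted p = 0.0168, 10 of 12).

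Among other lists, 2 of 14 ER-stress miRNAs fell (1 adjusted over the list alone), miR-125b-5p (-0.56 ± 0.14, adjusted p = 0.0152) and miR-222-3p (-0.91 ± 0.33, adjusted p = 0.0399), which turned to 0.20 with the composition score as a term. Of 13 peripheral nerve injury miRNAs 1 rose and 3 fell (4 adjusted over the list alone), miR-155-5p against miR-30b-5p, miR-146a-5p and miR-222-3p. The erythroid miR-451a fell to 0.28 (-1.85 ± 0.51, adjusted p = 0.0196, 10 of 12) as 1 of 4 blood miRNAs (1 adjusted over the list alone). The smooth muscle miR-145a-5p and miR-145a-3p fell as 2 of 5 endothelium and vessel wall miRNAs (3 adjusted over the list alone). The oligodendrocyte miR-219a-5p fell to 0.19 (-2.43 ± 0.78, adjusted p = 0.0252, 10 of 12) as 1 of 4 (1 adjusted over the list alone). miR-19b-3p fell to 0.42 as 1 of 9 miR-17-92 miRNAs (1 adjusted over the list alone). Of 4 muscle miRNAs, miR-133a-3p/miR-133b-3p fell to 0.53 and miR-206-3p rose 1.61-fold (2 adjusted over the list alone). Of 6 choroid plexus miRNAs miR-449a-5p rose 1.48-fold (1 adjusted over the list alone). Both miR-206-3p and miR-449a-5p were more abundant in striatum and cerebellum than in cortex. Most of the cortex libraries rich in such marker miRNAs, named below, were injured ones. Other tissue in these libraries was therefore not excluded as a source of the 2 rises. The pituitary and hypothalamus list had 0 of 3 past the threshold (3 adjusted over the list alone). The Htr2c-hosted (0 of 4), miR-200 (0 of 4), miR-181 (0 of 4), miR-183 (0 of 2) and Hox (0 of 2) lists had 0 adjusted over the list alone as well. Apart from let-7, camera gave adjusted p-values from 0.243 to 0.972 for the lists tested, and from 0.911 to 0.98 with an estimated correlation. fry, which asks only whether a list moves on balance one way, gave an adjusted p of 0.025 for the let-7, microglia, neuron, miR-29 and ER-stress lists, 0.0473 for Dlk1-Dio3 and 0.0446 for the pituitary list. Median and mean log2 change had different signs for the miR-30 (0.05 and -0.37), nerve injury (0.02 and -0.19), endothelium (0.06 and -0.17) and muscle lists (0.07 and -0.02). For the choroid plexus (median -0.17) and miR-181 lists (median -0.04) camera's direction was up.

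The quasi-likelihood test of edgeR called 164 of 530 miRNAs in this comparison (58 rose, 106 fell, median size 0.61 log2 units), DESeq2 called 194 and limma voom 169. Upper-quartile scaling moved the median log2 change of all miRNAs from -0.028 to 0.084 and the split to 101 up and 66 down, with the sign of all 164 kept. Cortex libraries also differed by biol rep. The composition score, whose axis comes from the cerebellum, was -0.50 ± 0.51 in naive WT, 0.39 ± 0.31 in injured WT, -0.24 ± 0.79 in naive DYT1KI and 0.35 ± 0.72 in injured DYT1KI mice (mean ± SD, n = 6 each). With this score as a term 0 miRNAs passed (79 at an unadjusted p under 0.05). There miR-434-3p stood at -0.29 (adjusted p = 0.189), miR-212-3p at -0.10 (0.577) and let-7b-5p at 0.17 (0.434). Within biol rep 1 to 3 (6 injured against 6 naive libraries) edgeR called 211 (122 up, 89 down) and within 4 to 6 it called 124 (25 up, 99 down). miR-434-3p had -0.99 and -1.06 in these ranges (adjusted p = 6.6e-06 and 0.005) and miR-212-3p -0.63 and -0.57 (0.00115 and 0.00528). miR-155-5p had 0.58 and 0.51 (0.00221 and 0.0429), let-7b-5p 0.57 and 0.29 (0.00339 and 0.169), and miR-29a-3p -0.04 and -0.46 (0.821 and 0.0154). All 164 had the pooled sign within biol rep 1 to 3, as did all 162 of them still tested within 4 to 6. That sign is largely given, since they were chosen on the same libraries pooled.

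Single libraries weighed on the cortex count. It fell from 164 to 99 without biol rep 2 of the WT naive group, and to 107, 97 and 93 without biol rep 1, 4 and 6 of the WT crush group. It fell to 72 and 58 without biol rep 2 and 3 of the DYT1KI naive group, and to 25, 67 and 106 without biol rep 4, 5 and 6 of the DYT1KI crush group. The Htr2c-hosted miRNAs, scarce in cortex, averaged 2.47 ± 0.59 log2 CPM in naive WT, 3.29 ± 1.22 in injured WT, 3.50 ± 1.95 in naive DYT1KI and 3.29 ± 1.74 in injured DYT1KI mice (mean ± SD, n = 6 each). Without 4 libraries rich in these or in miR-449a-5p and miR-206-3p (WT crush biol rep 2, DYT1KI naive biol rep 1, DYT1KI crush biol rep 1 and 6) edgeR called 0 miRNAs, with 203 at an unadjusted p under 0.05 and a smallest adjusted p of 0.051. There all 164 kept their sign, with a median size of 0.56 in place of 0.61 and a median SE of 0.20 in place of 0.18, and miR-434-3p stood at -1.05 ± 0.28. The blood list averaged 3.57 ± 0.61, 2.94 ± 0.43, 3.02 ± 0.47 and 2.84 ± 0.33 log2 CPM in the same order of groups. The oligodendrocyte list averaged 5.84 ± 0.43, 4.82 ± 0.48, 5.76 ± 1.01 and 5.24 ± 1.07. miR-24-3p was counted in 8 of 24 cortex libraries, which were all 6 naive libraries of biol rep 1 to 3 and 2 injured ones. Without these 8 edgeR called 0, with 78 at an unadjusted p under 0.05, but this leaves 0 naive and 4 injured libraries of biol rep 1 to 3, so injury is mixed with the range there. Within biol rep 4 to 6, where 0 libraries held miR-24-3p, the count was 124.

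**Figure D2:**
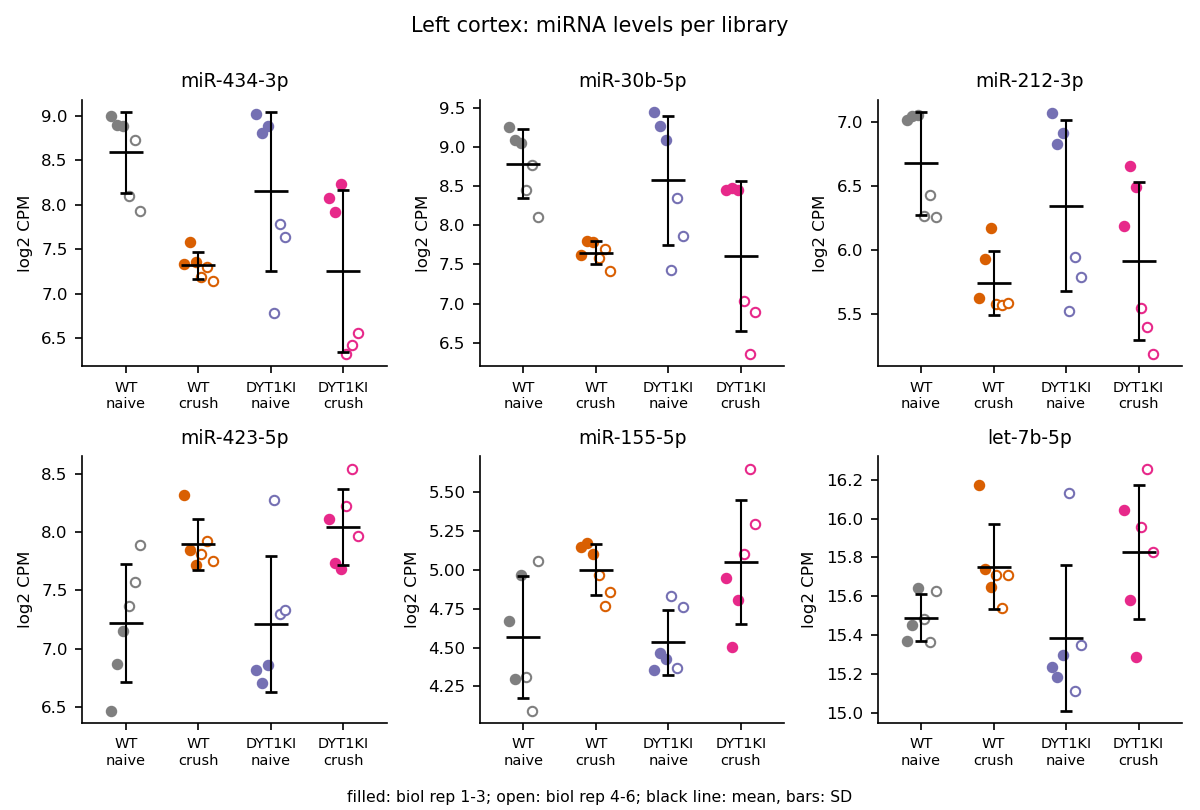
Log2 CPM of 6 miRNAs in the cortex of naive and injured WT and DYT1KI mice, with 1 point per library (filled for biol rep 1 to 3, open for 4 to 6), a black line at the mean and bars of 1 SD (n = 6 per group). miR-434-3p, miR-30b-5p and miR-212-3p are lower and miR-423-5p, miR-155-5p and let-7b-5p higher on average in the injured groups of both genotypes, with overlap between single libraries.

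**Figure D3:**
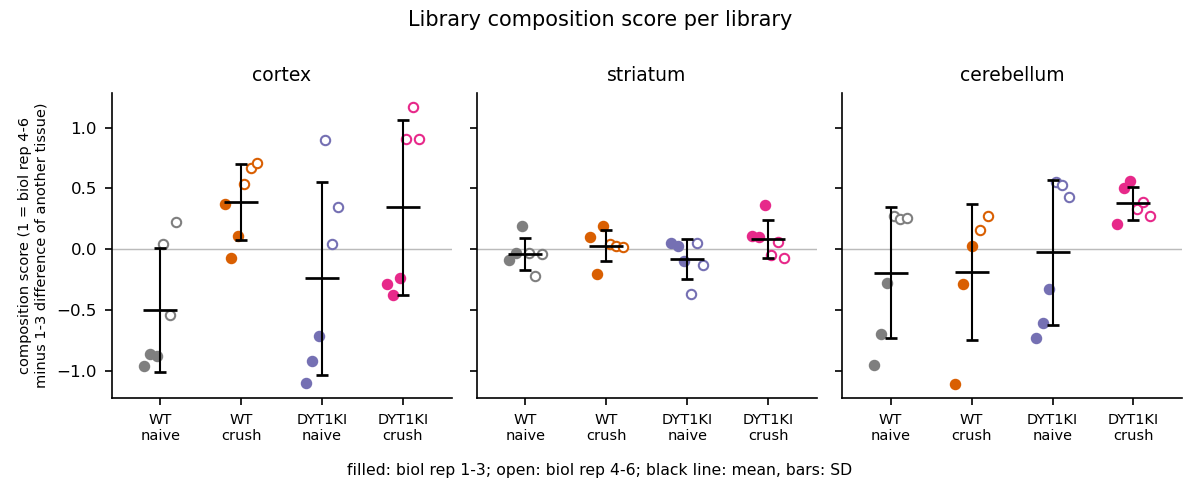
Composition score of each library in the 3 tissues, by group, where 1 on the vertical axis equals the difference between biol rep 4 to 6 and biol rep 1 to 3 of another tissue. Points are libraries (filled for biol rep 1 to 3, open for 4 to 6), lines are means and bars 1 SD (n = 6 per group, 5 in injured WT cerebellum). In cortex the injured groups average 0.39 and 0.35 and the naive groups -0.50 and -0.24, and in cerebellum the injured DYT1KI group averages 0.38.

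Within each genotype, whether cortical miRNAs passed the threshold after injury depended on the settings of edgeR. With the 4 groups fitted together, TMM scaling and no further term it called 0. With only the 2 groups compared it called 134 in WT and 0 in DYT1KI mice, with the animal number range as a term 237 and 104, and with DESeq2 size factors 0 and 2. The animal number range is uneven here, since only animal 31 of the naive WT mice falls in the low range. With biol rep 1 to 3 against 4 to 6 as a term edgeR called 172 in WT and about 1.5e+02 in DYT1KI mice. Within biol rep 1 to 3 it called 189 and 53, and within 4 to 6 it called 27 and 26. With the 4 groups together and no further term, in WT mice (6 against 6) the values with the smallest p were 0.68 for miR-5121, 0.87 for miR-1941-5p, 0.72 for miR-551b-5p, -0.94 for let-7d-3p, -0.54 for miR-125a-5p and -0.71 for miR-125b-2-3p, all at an adjusted p of 0.0598. In DYT1KI mice they were 0.56 for miR-125b-1-3p (adjusted p = 0.0832), 0.61 for miR-666-5p and 1.06 for miR-206-3p (0.0978 each). The negative ones were -1.18 for miR-218-2-3p (0.0737), -0.59 for miR-29a-3p (0.0832) and -0.71 for miR-29c-3p (0.0978). In that fit edgeR called 0 of 530 in WT (168 at an unadjusted p under 0.05), where DESeq2 called 84 and voom 0. It called 0 in DYT1KI mice (131), where DESeq2 called 43 and voom 0. Leaving out biol rep 4 of the DYT1KI naive group or biol rep 3 of the DYT1KI crush group gave 99 and 56 calls in DYT1KI mice, and leaving out biol rep 5 of the WT naive group gave 1. Leaving out biol rep 4 of the WT crush group gave 1 in WT mice. In DYT1KI mice camera called the let-7 family up (adjusted p = 0.000358, 6 of 9 members adjusted over the list alone, adjusted p = 0.877 with an estimated correlation). It called the miR-29 family down (adjusted p = 0.0428, 2 of 3 adjusted over the list alone, adjusted p = 0.877 with an estimated correlation). Adjusted over the list alone, WT mice had 5 Dlk1-Dio3, 5 microglia, 3 neuron, 3 ER-stress, 3 nerve injury and 2 miR-30 members past 0.05. The effects of both genotypes had a correlation of 0.59 across miRNAs, which are not independent replicates. Of the 50 miRNAs with the smallest p in WT mice 46 had the same sign in DYT1KI mice. The composition score also averaged higher after injury in WT (0.39 against -0.50) and in DYT1KI mice (0.35 against -0.24). A shared injury response can therefore not be told apart from a shared gradient here. The interaction, which asks whether the mutation changes the response to injury, had 0 calls by edgeR, DESeq2 and voom (20 at an unadjusted p under 0.05 in edgeR, smallest adjusted p 0.815). The smallest p belonged to miR-491-3p (2.99), miR-664-3p (1.01), miR-433-3p (0.79), miR-5121 (-0.98), miR-376b-3p (-0.54) and miR-141-3p (-2.46).

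Between DYT1KI and WT mice, no cortical miRNA passed the threshold by edgeR with all libraries and without a term for biol rep or animal number. In naive mice edgeR called 7 with the biol rep range and 46 with the animal number range as a term, and 0 within either biol rep range. In injured mice it called 0 with either term and 5 within biol rep 1 to 3. The animal number range is not balanced over genotypes in naive mice, where only animal 31 of the WT mice falls in the low range. Without the terms, in naive mice miR-20a-5p (0.37), miR-1264-3p (2.83), miR-511-3p (0.75), miR-184-3p (-0.49), miR-666-5p (-0.42) and miR-664-3p (-0.68) had the smallest p, all at an adjusted p of 0.746. In injured mice these were miR-491-3p (2.74), miR-449a-5p (0.79), miR-206-3p (0.72), miR-5121 (-0.51), miR-141-3p (-1.46) and miR-10b-5p (-0.52), at 0.996. Averaged over treatments they were miR-1264-3p (1.81), miR-449a-5p (0.47), miR-448-3p (2.06), miR-669k-5p (-0.46), miR-10b-5p (-0.46) and miR-144-3p (-0.73), at 0.99. miR-1264-3p and miR-448-3p are Htr2c-hosted, a list that was high in single cortex libraries. It averaged 7.41 log2 CPM in DYT1KI naive biol rep 1 (2.45 to 3.46 in the others of the group). The values were 6.76 in DYT1KI crush biol rep 6 (2.2 to 3.18) and 5.66 in WT crush biol rep 2 (2.26 to 3.37). edgeR, DESeq2 and voom called 0 in all of these comparisons, with 24, 10 and 14 at an unadjusted p under 0.05 in edgeR. In injured mice camera called the miR-200 family (adjusted p = 0.0186) and the miR-29 family (adjusted p = 0.0435) lower in DYT1KI, each with an adjusted p = 0.797 with an estimated correlation. Averaged over treatments it called the miR-17-92 list higher (adjusted p = 0.0343, adjusted p = 0.181 with an estimated correlation). The miR-200 and miR-17-92 lists had 0 members past 0.05 adjusted over the list alone.

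In the cerebellum, DYT1KI mice had more let-7 than WT mice, averaged over naive and injured animals (12 DYT1KI against 11 WT libraries). Of the 8 let-7 members called, 0 passed with the composition score as a term and 0 within either biol rep range. let-7a-5p rose 1.46-fold (0.54 ± 0.13 log2 units, adjusted p = 0.0267) and was above the WT mean of its treatment in 12 of 12 DYT1KI libraries. Its level was 86400 ± 12000 CPM in naive WT (mean ± SD, n = 6), 85900 ± 16900 in injured WT (n = 5), 125000 ± 24400 in naive DYT1KI and 126000 ± 41400 in injured DYT1KI mice (n = 6 each). The let-7 list held 50.9% of the counts in naive WT, 49.2% in injured WT, 58.2% in naive DYT1KI and 56.7% in injured DYT1KI mice. The 10 most abundant miRNAs, let-7 members among them, held 67.2%, 68.2%, 72.9% and 72.3%, and without let-7 the 10 most abundant held 64.5%, 67.1%, 66.4% and 67.1% of the rest. let-7b-5p rose 1.53-fold (0.62 ± 0.15, adjusted p = 0.0283, 12 of 12) and miR-206-3p 1.52-fold (0.60 ± 0.14, adjusted p = 0.0267, 11 of 12). The erythroid miR-144-3p fell to 0.33 of the WT level (-1.58 ± 0.36, adjusted p = 0.0267, 12 of 12). It went from 25.3 ± 21 CPM in naive WT and 11.7 ± 11 in injured WT to 6.9 ± 2.13 and 4.83 ± 1.85 in DYT1KI mice. miR-136-3p of the imprinted Dlk1-Dio3 region fell (-0.43 ± 0.10, adjusted p = 0.0267, 12 of 12).

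The let-7 family had 8 of 9 members that rose (9 adjusted over the list alone), between 1.33-fold for let-7d-5p (0.41 ± 0.11, adjusted p = 0.0312) and 1.53-fold for let-7b-5p. miR-98-5p at 0.45 ± 0.13 was just outside (adjusted p = 0.0505). camera gave the family an adjusted p of 1.51e-06, but an adjusted p = 0.484 with an estimated correlation, and fry gave 0.0231. Of the miR-29 family, repressors of collagens, miR-29a-3p fell to 0.77 (-0.38 ± 0.11, adjusted p = 0.0367, 10 of 12) as 1 of 3 (2 adjusted over the list alone, camera adjusted p = 0.0517, fry 0.0231). Of 10 microglia and inflammation miRNAs the blood-cell miR-142a-5p fell to 0.74 (-0.44 ± 0.13, adjusted p = 0.0495, 12 of 12; 3 adjusted over the list alone, camera adjusted p = 0.0517, fry 0.0258). miR-146a-5p had -0.65 ± 0.21 (adjusted p = 0.0631) and miR-155-5p 0.34 (adjusted p = 0.186). Single members rose in 5 further lists, miR-206-3p of 4 muscle miRNAs (2 adjusted over the list alone) and miR-204-3p of 7 choroid plexus miRNAs (0.57 ± 0.16, adjusted p = 0.0367, 11 of 12; 1). The others were miR-129-5p of 10 neuron-enriched miRNAs (0.49 ± 0.13, adjusted p = 0.0336, 11 of 12; 1) and miR-485-5p of 9 activity-regulated (3) and of 39 Dlk1-Dio3 miRNAs (0.50 ± 0.14, adjusted p = 0.0367, 11 of 12; 4). miR-144-3p was 1 of 4 blood miRNAs that fell (3 adjusted over the list alone), and miR-451a stood at -1.77 ± 0.65 (adjusted p = 0.089). The endothelium (of 5), ER-stress (15), Hox (4), Htr2c-hosted (5), miR-17-92 (9), miR-181 (4), miR-183 (3), miR-200 (4), miR-30 (5), nerve injury (14) and pituitary (3) lists had 0 members past the threshold and 0 adjusted over the list alone. The oligodendrocyte list had 0 of 4 (2 adjusted over the list alone). Their camera adjusted p-values, with those of the muscle, choroid plexus, neuron, activity, Dlk1-Dio3 and blood lists, lay between 0.185 and 0.998, and between 0.879 and 0.999 with an estimated correlation. Median and mean differed in sign for the activity (-0.04 and 0.04, direction up), miR-17-92 (0.01 and -0.12, down) and miR-30 lists (0.07 and -0.18, down). camera's direction was down for the miR-183 list (0.13 and 0.02). miR-132-3p (-0.04, adjusted p = 0.937), miR-212-3p (-0.32, 0.379), miR-21a-5p (-0.18, 0.302), miR-124-3p (-0.09, 0.636) and miR-9-5p (-0.12, 0.329) did not pass.

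Besides these, miR-323-5p (0.86 ± 0.21), miR-139-3p (0.64 ± 0.15) and miR-7689-3p (0.37 ± 0.09) rose and miR-3106-5p (-0.61) fell at an adjusted p of 0.0267. miR-7668-3p, among the calls, was at 0 in 11 of 11 WT libraries and had 11 to 22 counts in 7 of 12 DYT1KI libraries, so no fold is given. edgeR called 28 of 555 miRNAs (20 rose, 8 fell, median size 0.53), DESeq2 68 and voom 23. Upper-quartile scaling gave 15 up and 10 down with the sign of all 28 kept. The composition score, on the cortex axis, was -0.19 ± 0.54 in naive WT, -0.19 ± 0.56 in injured WT, -0.03 ± 0.60 in naive DYT1KI and 0.38 ± 0.13 in injured DYT1KI mice. With it as a term edgeR called 10, of which 7 were among the 28. There miR-206-3p stood at 0.45 (adjusted p = 0.0475), let-7a-5p at 0.42 (0.0626) and miR-144-3p at -0.98 (0.114). Within biol rep 1 to 3 and within 4 to 6 edgeR called 0 (147 and 81 at an unadjusted p under 0.05), with all 28 of the pooled sign in both. That sign is largely given, since the 28 were chosen on the same libraries pooled. let-7a-5p had 0.56 and 0.38 (adjusted p = 0.104 and 0.319), let-7b-5p 0.62 and 0.45 (0.105 and 0.181), miR-206-3p 0.58 and 0.46 (0.104 and 0.181) and miR-144-3p -2.16 and -0.71 (0.104 and 0.424). With the biol rep range as a term edgeR called 74, and with the animal number range, which is uneven over the groups, 169. With no filter on low counts it called 0 (193 at an unadjusted p under 0.05, smallest adjusted p 0.057), and with a filter at 10 CPM 54. The count was 0 without biol rep 2 of WT crush, biol rep 4 or 5 of DYT1KI naive, or biol rep 2 or 5 of DYT1KI crush. In the WT naive group it was 9 without biol rep 1 or 2 and 17 without biol rep 4. In the WT crush group it was 11, 12 and 45 without biol rep 1, 3 and 5. Biol rep 1 of WT crush, which stood apart in other miRNAs too, was lowest in let-7b-5p, and without it let-7b-5p had 0.53 ± 0.13 and let-7a-5p 0.49 ± 0.13 (adjusted p = 0.0454 each), with 3 of 8 let-7 members still called. It was 70 without biol rep 2 of DYT1KI naive, and 51 and 43 without biol rep 1 and 6 of DYT1KI crush.

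**Figure D4:**
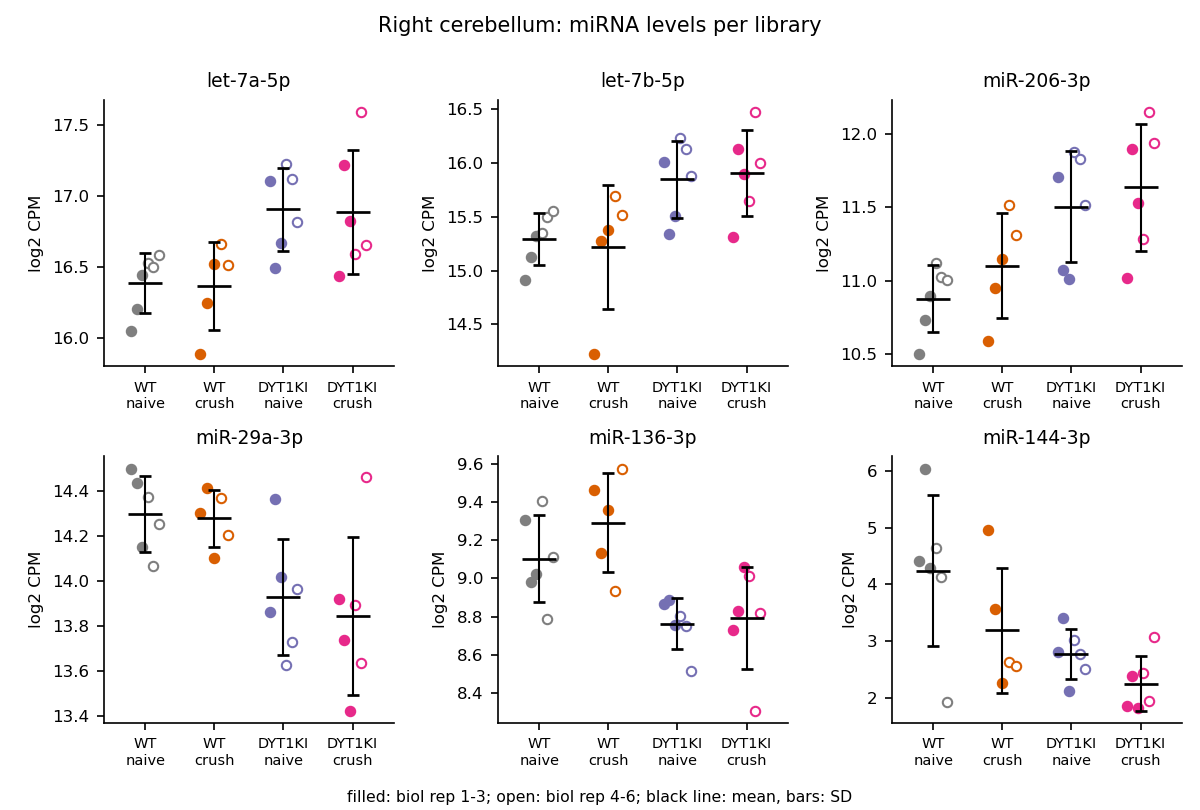
Log2 CPM of 6 miRNAs in the cerebellum of naive and injured WT and DYT1KI mice, with 1 point per library (filled for biol rep 1 to 3, open for 4 to 6), a black line at the mean and bars of 1 SD (n = 6 per group, 5 in injured WT). let-7a-5p, let-7b-5p and miR-206-3p are higher and miR-29a-3p, miR-136-3p and miR-144-3p lower on average in both DYT1KI groups than in the WT group of the same treatment, with overlap between single libraries.

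In naive mice alone, the cerebellum of DYT1KI and WT animals had its smallest p-values for miR-206-3p (0.65), let-7d-5p (0.45), let-7a-5p (0.53), miR-144-3p (-1.87), miR-3106-5p (-0.64) and miR-153-5p (-0.49), all at an adjusted p of 0.331. In injured mice alone they were those of miR-204-3p (0.81), miR-139-3p (0.74), miR-136-3p (-0.50), miR-219a-5p (-4.53) and miR-329-3p (-1.61), at 0.162. edgeR called 0 in naive (65 at an unadjusted p under 0.05) and 0 in injured mice (122), where DESeq2 called 11 and 0 and voom 0 and 0. With the animal number range as a term edgeR called 1 in naive and 35 in injured mice, and with the composition score 1 and 0. Without biol rep 6 of WT naive or biol rep 2 of DYT1KI naive edgeR called 1 in naive mice. camera called let-7 higher in naive DYT1KI mice (adjusted p = 4.64e-07, 9 of 9 adjusted over the list alone, adjusted p = 0.661 with an estimated correlation). It did so in injured ones (adjusted p = 0.000273, 9 of 9 adjusted over the list alone, adjusted p = 0.646 with an estimated correlation), and called the miR-200 family lower in injured DYT1KI mice (adjusted p = 0.0149, 2 adjusted over the list alone, adjusted p = 0.646 with an estimated correlation).

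In the cerebellum, edgeR called no miRNA after nerve injury with all libraries and no further term. With the composition score as a term it called 1 in WT mice, 0 in DYT1KI mice and 1 averaged over genotypes. Within biol rep 1 to 3 it called 67 in DYT1KI mice, 0 in WT mice and 32 averaged over genotypes, and within 4 to 6 it called 0. In biol rep 1 to 3 the composition score was 0.21, 0.50 and 0.56 in injured and -0.73, -0.61 and -0.33 in naive DYT1KI mice. Injury and composition can therefore not be told apart there. With all libraries and no further term, in WT mice (5 against 6) miR-181a-5p (0.49), miR-664-3p (1.62), miR-486a-5p/486b-5p (0.66), miR-1264-3p (-0.53) and miR-542-3p (-0.84) had the smallest p, at an adjusted p of 1. In DYT1KI mice these were miR-1912-3p (1.06), miR-879-3p (0.39), miR-149-5p (0.44), miR-325-5p (-0.72), miR-29b-1-5p (-0.88) and miR-466c-5p (-0.82), at 0.543. Averaged over genotypes they were miR-149-5p (0.38), miR-676-5p (0.47), miR-93-3p (0.43), miR-340-5p (-0.23), miR-384-5p (-0.31) and miR-29b-1-5p (-0.67), at 0.49. For the interaction they were miR-1912-3p (1.11), miR-1298-5p (0.87), miR-1264-3p (0.70), miR-664-3p (-1.96), miR-219a-5p (-4.07) and miR-466c-5p (-0.98), at 0.921. edgeR, DESeq2 and voom called 0 in these comparisons, with 21, 41, 41 and 14 at an unadjusted p under 0.05 in edgeR. camera called the miR-181 family up in injured WT mice (adjusted p = 6.38e-05, 2 adjusted over the list alone, adjusted p = 0.329 with an estimated correlation). The family was also called up averaged over genotypes (adjusted p = 0.0463, 2 adjusted over the list alone, adjusted p = 0.904 with an estimated correlation), where the microglia list was down (adjusted p = 0.0416, adjusted p = 0.599 with an estimated correlation). The Htr2c-hosted miRNAs were called down in injured WT mice (adjusted p = 0.0183) and the miR-200 family up (adjusted p = 0.0183), each with an adjusted p = 0.447 with an estimated correlation. In injured DYT1KI mice the Htr2c-hosted list was called up (adjusted p = 0.0156, 2 adjusted over the list alone, adjusted p = 0.587 with an estimated correlation). In the interaction the calls were Htr2c-hosted up (adjusted p = 1.5e-05, 4 of 5 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), miR-200 down (adjusted p = 0.000155, adjusted p = 0.292 with an estimated correlation) and miR-181 down (adjusted p = 0.0225, adjusted p = 0.589 with an estimated correlation).

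In the striatum, a main input station of the basal ganglia, neither injury nor genotype moved a miRNA past the threshold by edgeR with all libraries, the filter as described and no further term. With a filter at 10 CPM 1 miRNA passed for injury averaged over genotypes. After injury in WT mice the miR-200 family members miR-200a-3p (1.21) and miR-141-3p (1.5) and the sensory miR-182-5p (0.87) led the positive values, and miR-434-3p (-0.37) and miR-29b-2-5p (-0.38) the negative ones, at an adjusted p of 0.794, beside miR-195a-5p (-0.29, 0.81). In DYT1KI mice miR-151-5p (0.31), miR-26b-5p (0.17) and miR-3095-3p (0.52) had an adjusted p of 0.551. There 3 miRNAs of the imprinted Dlk1-Dio3 region led the negative values, miR-382-3p (-0.77, 0.162), miR-487b-3p (-0.56, 0.457) and miR-411-3p (-0.47, 0.457). Averaged over genotypes, miR-434-3p (-0.39, 0.105), miR-382-3p (-0.45, 0.286) and miR-411-3p (-0.34, 0.286) stood against the endothelial miR-126a-3p (0.15, 0.286), miR-130a-3p (0.20, 0.385) and miR-1224-5p (0.32, 0.408). Between genotypes the smallest p belonged to miR-3102-3p (0.64), miR-365-3p (0.58), miR-3062-5p (0.62), miR-296-3p (-0.38), miR-203-3p (-0.74) and miR-199a-3p/199b-3p (-0.31) in naive mice, at 0.975. In injured mice it belonged to miR-667-3p (0.88), miR-1306-5p (0.98), miR-543-3p (0.53, 0.33), miR-3059-3p (-0.46), miR-200a-3p (-1.35) and miR-141-3p (-1.55, 0.33), the others at 0.321. Averaged over treatments these were miR-3102-3p (0.63) and miR-365-3p (0.55) at 0.191, miR-667-3p (0.68, 0.287), miR-3059-3p (-0.31, 0.271), miR-3473b/3473e (-0.44, 0.287) and miR-296-3p (-0.25, 0.417). For the interaction they were miR-677-5p (0.65), miR-203-3p (0.76), miR-200a-3p (-1.38), miR-382-3p (-0.64) and miR-190a-5p (-0.39) at 0.872.

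The counts behind the striatum were 0 of 547 by edgeR in all 7 comparisons in that fit. At an unadjusted p under 0.05 there were 29 after injury in WT, 46 in DYT1KI mice, 54 averaged over genotypes, 15 between genotypes in naive and 72 in injured mice, 53 averaged over treatments and 16 for the interaction. DESeq2 called 1 for the averaged injury effect and 0 elsewhere, and voom called 0. Within biol rep 4 to 6 edgeR called 2 between genotypes in naive mice and 2 averaged over treatments. Without biol rep 6 of DYT1KI crush edgeR called 1 after injury in DYT1KI mice and 1 averaged over genotypes, and without biol rep 3 of WT naive it called 1 averaged over genotypes. camera called the miR-200 family up after injury in WT mice (adjusted p = 0.0135, 4 of 4 adjusted over the list alone, adjusted p = 0.672 with an estimated correlation). The family was called lower in injured DYT1KI than injured WT mice (adjusted p = 0.0438, 3 of 4 adjusted over the list alone, adjusted p = 0.802 with an estimated correlation). let-7 was called up after injury in DYT1KI mice (adjusted p = 0.0338, 0 adjusted over the list alone, adjusted p = 0.663 with an estimated correlation). The simulated striatum data recovered 67.7% of 1.5-fold changes for a comparison within WT mice. With 200 miRNAs changed and each drawn on its own, that share does not give the power for few changes or miRNAs that vary together.

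Whether the mutation or the injury acts differently between tissues was tested with limma voom over 629 miRNAs. The genotype difference of naive mice differed between cortex and cerebellum for 19 miRNAs, with miR-29a-3p at 0.76, the imprinted miR-154-5p at 0.72 and miR-376b-3p at 0.86, and the blood-cell miR-142a-5p at 0.75 log2 units (cortex minus cerebellum). The response of DYT1KI mice to injury differed between the same tissues for miR-154-5p (-0.84). The other 10 contrasts between tissues had 0 calls by voom, with 17 to 115 miRNAs at an unadjusted p under 0.05. The smallest adjusted p of these, 0.0597, belonged to the injury effect of WT mice between cortex and striatum. Without the correlation between tissues of a mouse the 19 became 15 and the 1 became 0. All 19 differences were positive, and other scalings or the composition score were not run in this fit. Within a tissue, edgeR called 0 between genotypes of naive mice in cortex and in cerebellum (smallest adjusted p 0.746 and 0.331).

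In the authors' deposited tables, the cortex held all miRNAs below an adjusted p of 0.05. The authors' deposited table for injury in WT cortex listed 48 such miRNAs (10 up, 38 down) and that for injury in DYT1KI cortex 27 (6 up, 21 down). Each of the other 10 authors' deposited tables listed 0. These come from DESeq2 per the file headers, where the edgeR test above called 0 in both comparisons and DESeq2 with the settings used here called 84 and 43.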

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

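Of the tests in this part, those that ask whether the composition gradient is the whole cause, those of depth, animals and locus for miR-24-3p, and the settings without some libraries or with the score as a term were chosen after the result had been seen. The gradient and GC correlations were set out before their values were known, but after the principal components had shown the gradient.

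The first pattern is the injury effect in the cortex, with 164 miRNAs called, among them lower miR-434-3p and higher let-7. Of 100 splits of the libraries 1, the real one, gave as many (highest other 23), which argues against chance. It does not exclude chance, since 100 splits can give no smaller share and comparisons were made in every tissue. The tables argue against a scaling shift by miRNAs that are at 0 in part of the libraries, since about 1.6e+02 were called without them. A composition gradient may account for the pattern: the called fold changes followed the difference between biol rep 4 to 6 and 1 to 3 of the cerebellum (Pearson r = 0.72 across miRNAs, which are not independent, 151 of the same sign), and with the score as a term the median size fell from 0.61 to 0.19, while the median SE went from 0.18 to 0.13, so the size was 1.5 times the SE and 0 were called. GC content cannot be told apart as a contributor, because r with GC was 0.25, between the bounds set for yes and no. An injury response that happens to run along the same direction would also be removed by the score, so it stays open, also because 211 and 124 were called within biol rep 1 to 3 and 4 to 6. Within each of these ranges, though, every injured library had a higher score than every naive one of its genotype.

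The second pattern is the genotype effect in the cerebellum, with 28 miRNAs called, 8 of them let-7 members. Here 1 of 100 splits, the real one, gave as many (highest other 0), which argues against chance. It does not exclude chance, since 100 splits can give no smaller share and comparisons were made in every tissue. Whether the gradient shared with the cortex is the whole cause cannot be decided for the 28 as a set. With the score as a term the median size went from 0.53 to 0.40 and the median SE from 0.14 to 0.11. The size stayed 3.6 times the SE, past the bound set for no, and 10 were called, 7 of them among the 28. But the 28 were chosen for a large size over SE in these same libraries. The score, on an axis of another tissue, may also remove the gradient only in part. For let-7 the gradient as the whole cause stays open too, since 0 of the 8 members were still called (size 0.50 to 0.35, SE 0.13 to 0.11, adjusted p of 0.0571 or more). The gradient may add to the others, since the called fold changes followed the cortex gradient (r = 0.72, 22 of 27 of the same sign). GC content (r = 0.24) cannot be told apart, since it too lies between the bounds. An effect of the mutation on let-7 in the cerebellum therefore stays open, with 0 calls without any of 5 single libraries as a limit. Within biol rep 1 to 3 and 4 to 6 the 28 had a median size of 0.53 and 0.39 and a median SE of 0.18 and 0.15, with 0 called. They kept their sign there, which is largely given, since they were chosen on the same libraries pooled.

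The third pattern is miR-24-3p, which was counted in 10 of 71 libraries and listed at 0 in the others: 8 of cortex (11170 to 13740 CPM), 2 of cerebellum (7225 and 6026 CPM) and 0 of striatum, all of biol rep 1 to 3. Depth is excluded, because the smallest count expected in any library at 0 was 54320. Of miRNAs higher in every cortex library without miR-24-3p than in every one with it, the largest rise in median CPM was 41.2. This argues against a move of its reads to a single listed miRNA that varies little. It cannot exclude a move to an abundant miRNA that varies between libraries, or to several miRNAs. A difference between animals is excluded, since 9 animals had miR-24-3p in some tissue and lacked it in another. A true change of the locus is argued against by its neighbours in the same transcripts, which kept 0.44 (miR-23a-3p/23b-3p, 1190 against 523 CPM) and 0.56 (miR-27a-3p/27b-3p) of their level. How reads of miR-24-3p were assigned before the counts were made was not tested and stays open.

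Single libraries stood apart from their group in 24 of 252 tests, each of a single quantity in a single group. The test took the gap to the nearest library relative to the range, and about 13 are expected by chance. Many tests share libraries, so they are not independent. The libraries that stood apart are given by group and biol rep as log2 CPM against the range of the other libraries. In the cortex these were miR-124-3p in WT naive 5 (15.1 against 15.5 to 15.8) and in DYT1KI naive 4 (14.7 against 15.5 to 15.8). Others were the miR-200 list in WT naive 3 (2.72 against 1.85 to 2.16), miR-423-5p in WT crush 1 (8.32 against 7.72 to 7.92) and the pituitary list in WT crush 3 (8.44 against 8.7 to 8.81). The Htr2c-hosted list was high in the cortex of WT crush 2 (5.66 against 2.26 to 3.37), DYT1KI naive 1 (7.41 against 2.45 to 3.46) and DYT1KI crush 6 (6.76 against 2.2 to 3.18). In the striatum they were miR-146a-5p in DYT1KI naive 1 (4.9 against 5.27 to 5.43), and miR-124-3p and the Htr2c-hosted list in DYT1KI naive 4 (15.3 against 14 to 14.3, and 4.53 against 4.84 to 5.02). The choroid plexus and microglia lists stood apart there in DYT1KI crush 3 (5.06 against 5.57 to 5.77, and 4.74 against 4.95 to 5.08). In the cerebellum WT crush 1 was high in miR-132-3p (7.25 against 5.66 to 6.03), miR-212-3p (3.76 against 1.92 to 2.41), miR-21a-5p (10.4 against 9.3 to 9.56), the blood list (4.71 against 2.71 to 3.26) and the endothelium list (9.51 against 9.06 to 9.11). Further cerebellar values were miR-136-3p in DYT1KI naive 6 (8.51 against 8.75 to 8.89) and miR-3106-5p in DYT1KI naive 2 (1.7 against 0.542 to 0.964). The choroid plexus list stood apart in DYT1KI crush 3 (5.36 against 4.78 to 4.98) and the oligodendrocyte list in DYT1KI crush 1 (5.14 against 4.12 to 4.43). The cerebellum of DYT1KI crush 6 had the fewest total counts of its group (8.2 Mcounts against 11 to 11.6) and a high blood list (3.98 against 2.33 to 2.8).

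Effects that differed between tissues by limma voom all concerned cortex against cerebellum. For DYT1KI against WT in naive mice the differences of the log2 changes, cortex minus cerebellum, were 0.76 for miR-153-5p, 0.69 for miR-20a-5p, 0.86 for miR-376b-3p, 0.55 for miR-3068-5p, 0.70 for miR-425-3p, 1.32 for miR-490-3p, 0.98 for miR-701-5p, 2.69 for miR-218-2-3p, 0.72 for miR-154-5p, 0.78 for miR-450a-5p, 0.73 for miR-300-3p, 0.75 for miR-142a-5p, 0.76 for miR-29a-3p, 0.85 for miR-107-5p, 0.59 for miR-138-5p, 1.12 for miR-210-3p, 2.24 for miR-1191a, 1.02 for miR-147-3p and 0.70 for miR-666-3p. For injury in DYT1KI mice it was -0.84 for miR-154-5p.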

How the results depend on the processing

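The terms for biol rep ranges, the ranges alone, the composition score and the settings without some miRNAs or libraries were chosen after the data had been seen, and the other settings before. Across the named miRNAs 13665 values kept their direction and side of the threshold, 1006 lost the threshold and 183 gained it. Another 309 turned direction without passing the threshold in either fit. Of values past the threshold in at least 1 of the fits, 11 turned direction, all in the cortex injury effect. With the composition score as a term these were miR-212-5p (0.01), miR-136-5p (0.16), miR-329-3p (0.08), miR-410-3p (0.14), miR-494-3p (0.00), miR-496a-3p (0.05), miR-543-3p (0.06) and miR-222-3p (0.20). Without the miR-24-3p libraries they were miR-329-3p (0.03), miR-410-3p (0.09) and miR-222-3p (0.07). The tissue comparisons of naive WT mice stayed within 1.5 times under the settings tried. The cause of the changes below was not tested unless the setting itself has fewer miRNAs or libraries.

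The animal number range is uneven over the groups, so its counts below are not read as better adjusted. In place of 164 calls, the cortex injury effect had 277 with the animal number range as a term and 0 with the composition score, without the miR-24-3p libraries (16 left) or without the marker-rich libraries. The miR-24-3p setting says nothing on injury, since it leaves 0 naive but 4 injured libraries of biol rep 1 to 3. Without the marker-rich libraries all 164 kept their sign and the median size went from 0.61 to 0.56 and the median SE from 0.18 to 0.20, so the calls ended just outside the threshold (smallest adjusted p 0.051). The cerebellum genotype effect had 0 in place of 28 with no filter, 54 at 10 CPM or more, 68 by DESeq2, 169 with the animal number range, 74 with the biol rep range as a term, 0 within biol rep 1 to 3, 0 within 4 to 6 and 10 with the score. Where 0 had been called, injury in WT cortex had 84 by DESeq2, 134 with only the 2 groups compared, 237 with the animal range, 172 with the biol rep range as a term and 189 and 27 within the ranges. Injury in DYT1KI cortex had 2 with DESeq2 size factors, 43 by DESeq2, 104 with the animal range, about 1.5e+02 with the biol rep range and 53 and 26 within the ranges. Genotype in naive cortex had 46 with the animal range and 7 with the biol rep range, and in injured cortex 5 within biol rep 1 to 3. In striatum the averaged injury effect had 1 at 10 CPM or more and 1 by DESeq2. Within biol rep 4 to 6 the genotype effect had 2 in naive mice and 2 averaged. In cerebellum, genotype in naive mice had 11 by DESeq2, 1 with the animal range and 1 with the score. Genotype in injured mice had 35 with the animal range, injury in DYT1KI mice 67 within biol rep 1 to 3, the averaged injury effect 32 within biol rep 1 to 3 and 1 with the score, and injury in WT mice 1 with the score. Within biol rep 1 to 3 injury cannot be told apart from the composition score in the cerebellum of DYT1KI mice. An estimated correlation took the 22 list calls to 0. In the authors' deposited tables the 75 calls were 48 with a fold of at least 1.5 and 275 at an adjusted p under 0.1.

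With the biol rep number as a block, the calls were 240 for cortex injury (164 without it), 164 for injury in WT and 119 in DYT1KI cortex, 3 for genotype in naive cortex, 1 for injury in DYT1KI striatum, 1 for averaged injury in striatum and 89 for cerebellum genotype. The numbers do not pair the mice, since they stand for different animals and not every pair deviates together. Of pairs of the same number, 30 of 36 in cortex, 20 of 33 in cerebellum and 3 of 36 in striatum correlated above 0.1. In cortex, libraries of another number in the same range (mean r 0.28) did so as much as those of the same number (0.29). In cerebellum the mean was 0.15 for the same number and 0.08 for another number in the same range.

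Leaving out each library in turn gave 25 to 220 calls for cortex injury, 0 to 1 for injury in WT cortex, 0 to 99 in DYT1KI cortex, 0 to 1 for injury in DYT1KI striatum and averaged in striatum, 0 to 1 for genotype in naive cerebellum and 0 to 70 for cerebellum genotype. An alternative limited to miRNAs was not run, as the tables hold no other class. Depth of 5182284 counts or more put most tested miRNAs far above 3 counts, and the lowest chi-square per degree of freedom between replicates was 16.37, so libraries differed by more than counting noise.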

Other observations

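The relations in this part were chosen after the data had been seen. Blood-cell miRNAs varied between mice across tissues. miR-451a and miR-144-3p, processed from 1 erythroid transcript, differed between mice of the same group, and mice high in 1 tissue tended to be high in another. Over 23 mice, miR-451a of cortex and cerebellum had Pearson r = 0.74 after subtraction of group means (permutation p = 5e-05, adjusted p = 3e-04 over 6 relations, Spearman rho = 0.75, permutation p = 9e-05). It was 0.69 without the 2 farthest mice, and 0.62 and 0.64 within biol rep 1 to 3 and 4 to 6. miR-144-3p of striatum and cerebellum had r = 0.70 (permutation p = 0.00021, adjusted p = 0.00063, rho = 0.67, permutation p = 0.00074). It was 0.62 without the 2 farthest and 0.81 and 0.66 within the ranges. For miR-144-3p, cortex and striatum (r = 0.53, permutation p = 0.0073, adjusted p = 0.011, rho = 0.50, permutation p = 0.014, 24 mice) and cortex and cerebellum (r = 0.58, permutation p = 0.0031, adjusted p = 0.0063, rho = 0.36, permutation p = 0.09) fell to 0.28 and 0.27 without the 2 farthest mice, so these relations rest on them. They were 0.70 and 0.33, and 0.69 and 0.24, within the ranges. For miR-451a, cortex and striatum (r = 0.31, permutation p = 0.14, adjusted p = 0.138, rho = 0.27, permutation p = 0.2, 0.26 without the 2 farthest, 0.80 and 0.29 within the ranges) and striatum and cerebellum (r = 0.32, permutation p = 0.13, adjusted p = 0.138, rho = 0.33, permutation p = 0.13, 0.44 without the 2 farthest, 0.67 and 0.26 within the ranges) did not pass. Biol rep 2 of the WT naive group was the highest of its group in miR-144-3p in all 3 tissues, with 104 CPM in cortex, 25.5 in striatum and 65.5 in cerebellum.

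Libraries of biol rep 1 to 3 and 4 to 6 differed widely in cortex, where edgeR called 305 of 530 miRNAs between them (144 higher and 161 lower in 4 to 6), and in cerebellum with 204 of 555 (94 higher, 110 lower). In striatum edgeR called 0 of 547, with 13 at an unadjusted p under 0.05. In most groups biol rep 1 to 3 are also the low-numbered and 4 to 6 the high-numbered animals. Across miRNAs, which are not independent, the differences of cortex and cerebellum had r = 0.85 (490 miRNAs). Those of cortex and striatum had r = -0.41 (503 miRNAs) and those of striatum and cerebellum r = -0.47 (496 miRNAs). miR-3099-3p was another miRNA counted in part of the libraries only, in 10 of 24 of cortex (2001 to 4007 counts) and at 0 in 14. miR-337-3p was at 0 in 4 of 23 cerebellar libraries and had 470 to 1325 counts in the other 19. miR-377-3p was at 0 in 6 of 24 striatal libraries and had 81 to 210 counts in the rest. miR-6942-5p was at 0 in 22 of 24 striatal libraries, with 59 and 61 counts in the others. These 4 names were chosen after their values were seen. miR-7066-5p was at 0 in 2 of 24 striatal libraries (102 to 205 counts in the rest) and in 21 of 23 cerebellar ones (57 and 63 counts in the others), so its calls between tissues are not read as a tissue difference.

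Injury effects of both genotypes had a correlation of -0.04 across miRNAs in striatum and 0.15 in cerebellum, against 0.59 in cortex. Of the 50 miRNAs with the smallest p in WT mice 32 had the same sign in DYT1KI mice in striatum, 40 in cerebellum and 46 in cortex. Of the 50 with the smallest p in DYT1KI mice 38, 36 and 47 had the same sign in WT mice. The miRNAs of a tissue are not independent, so these counts carry no p. In cortex the composition score averaged higher in injured mice of both genotypes. The agreement there can therefore not be told apart from the gradient.

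For the comparisons of tissues in naive WT mice, 1 of 100 splits, the real one, gave as many calls. This is the smallest share that 100 splits can give and argues against chance. The counts were 148 with 79 as the highest other, 236 with 121 and 223 with 112. In the 19 comparisons with 0 calls all 100 splits give as many by construction, so these counts say nothing on chance. The highest count of another split was, in cortex, 95 for genotype in naive mice, 23 for genotype in injured mice, 1 and 44 for injury in WT and DYT1KI mice, 20 for averaged genotype and 46 for the interaction. In striatum it was 0, 5, 3, 4, 11 and 17 in that order, with 25 for averaged injury. In cerebellum it was 10, 0, 47 and 36, with 51 for averaged injury and 135 for the interaction. A structure of the samples may lie behind splits with many calls. Only their balance over the biol rep ranges was examined. Among splits whose groups, with genotypes or treatments pooled, draw on both biol rep ranges with a difference of at most 2 libraries, the highest cerebellar counts for injury were 0 in WT mice, 12 in DYT1KI mice, 41 averaged and 18 for the interaction. In cortex and striatum the highest counts were the same among such splits, and their cause was not tested.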
